A study of Homo sapiens with 4 samples.

How the data were processed

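Gene expression was measured in A172, an established human glioblastoma cell line. Per the labels, cells were transfected with an anti-miR directed against miR-196a-5p (anti-miR-196a below) or with its negative control, kept at 0.2% oxygen and collected 48 h after transfection. An anti-miR is a chemically modified oligonucleotide that pairs with a mature microRNA and blocks it. Each group had 2 samples. Total RNA (100 ng per sample) was amplified and biotin-labelled with a kit that primes at the poly-A tail, and 1 Affymetrix PrimeView array was hybridised per sample. The labels do not say whether the samples of a group came from separate cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. The number of arrays, 4 in all, limits the precision.

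Values of 49372 probe sets per array were deposited on the log2 scale with 2 decimals. Per the submitters' processing notes they were made with RMA, which corrects the background, normalizes the arrays by quantiles and summarises the probes of a set by median polish. The software version is not given in the sources used here, and no coordinates are printed because no genome build is named. RMA's summary can give the same value on several arrays, and rounding to 2 decimals adds further ties. Both make the spread of some genes 0. The authors' deposited table gave, for each probe set and group, the mean log2 value of both arrays, a signed linear fold change in which a fall is written as minus the inverse ratio, and an unadjusted p-value. The test behind that p-value is not given in the sources used here. Per the file headers its annotation is PrimeView release 36. Its mean levels lay above those of the per-array values by a median of 0.21 (log2) in anti-miR-196a and 0.215 in control samples. The per-array values and the table were therefore not on the same scale. Which processing step differed was not tested. Log2 differences from both sources correlated at r = 0.953 across probe sets, which are not independent replicates. Levels were never set across the sources.

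Of the 49372 probe sets, 79 were array controls. Among the other 49293, the annotation gave exactly 1 gene symbol for 46882, several for 1981 and none for 430. Genes were named only from probe sets with 1 symbol, and the probe set with the highest mean over the 4 arrays stood for its gene. This gave 18840 genes, of which 12202 had several probe sets. A total of 25 symbols had been turned into calendar dates by a spreadsheet and were not named. Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package (version 1.17.8), two-sided, as anti-miR-196a minus control, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. Gene lists were tested with camera at its preset correlation of 0.01 and adjusted over the 28 lists. At that setting camera sets a list's genes against the other genes and takes them as nearly independent. Its p-values then do not measure the spread between samples, and a shift of 1 sample can lower them. A list needed 5 measured members, and older symbols were matched through RefSeq gene names of GRCh38.p14. The lists held 627 genes, of which 18 were in more than 1 list. Each list's median was also set against 10000 random lists matched on mean expression in 20 bins. Drawings were made with matplotlib 3.10.9 in Python 3.11.15.

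The samples' groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named were, first, up to 15 genes per direction with the largest change among genes past the threshold. Where fewer passed, the places were filled by the genes with the smallest unadjusted p whose groups did not overlap and whose higher group had a mean log2 value of at least 6. Named were also up to 4 members per list with the largest absolute moderated t, and always NRAS, HOXC8, HOXA7, HOXB8, HMGA2, CDKN1B, NFKBIA, VEGFA, CA9 and MKI67. IFITM1, BST2, ISG15, OAS1, SEMA3D, AKR1C1, AKR1C2, AKR1C3, TAF9B, ENPP2, KRT8, KRT18 and CD68 were chosen after their values were seen. A planned test of genes with miR-196a seed sites in their 3′ untranslated region was not run, since transcript sequences were not used here. The genes it would have named are therefore not reported. A further gene that the rule names is not reported here. Alternatives were a replicate block, a filter that left out the dimmest 40% of genes, an intensity-dependent prior, quantile normalization applied again, arrays centred on their medians, the mean of a gene's probe sets, all probe sets, a fold threshold of 1.5, each array left out in turn, and, for lists, an estimated correlation and fry. Comparisons among the 3 arrays with poly-A spike-in signal, and the correlation of arrays over genes with a mean log2 value of at least 6, were added after seeing the data.

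The tests were tried on simulated data with 200 changed genes among 18840, in 2 arrays against 2. With the spread taken from all 4 arrays, 0% of genes changed by 1.5-fold, 31% of those changed by 2-fold and 63.5% of those changed by 4-fold were recovered. With the spread of the 3 arrays that carry poly-A spike-in signal the shares were 41%, 64% and 84.5%. False calls numbered 0, 1 and 3 with the first spread and 7, 11 and 15 with the second. Genes were drawn independently, with the same spread in both groups. The trials therefore do not cover a shift shared by many genes on 1 array. A list of 25 genes shifted by 1 log2 unit was recovered by camera with the preset correlation. With an estimated correlation its adjusted p was 0.437, so that setting did not recover a real shift of this size in 4 arrays.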

Results

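Transcript levels of 18840 genes were measured on 4 PrimeView arrays. The samples were A172 glioblastoma cells at 0.2% oxygen, 2 transfected with a negative control and 2 with anti-miR-196a. The array medians were 5.72 and 5.68 (log2) in control replicates 1 and 2 and 5.68 in both anti-miR-196a samples.

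Control replicate 1 stood apart from the other 3 arrays, including the other control. The interferon-induced transcripts IFITM1 and BST2 were at 12.04 and 9.25 (log2) in this sample. In the other control they were at 7.69 and 5.13, and in the anti-miR-196a samples at 7.23 and 7.58 for IFITM1 and at 4.95 and 5.16 for BST2. SEMA3D, a secreted guidance factor, was at 4.94 in control replicate 1 and at 8.04, 8.04 and 8.15 in the others. The proliferation marker MKI67 was at 8.41 in this sample and at 7.28, 7.44 and 7.40 in the others, while EGLN3, an oxygen-regulated prolyl hydroxylase, was at 8.01 against 9.78, 9.90 and 9.87.

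Between control replicate 1 and each other array, 369, 386 and 390 genes differed by at least 2-fold. Among the other 3 arrays, 1 gene differed by 2-fold between control replicate 2 and anti-miR-196a replicate 1, and 0 in the remaining pairs. The standard deviation of gene differences was 0.358 to 0.363 (log2) in pairs with control replicate 1. It was 0.102, 0.0937 and 0.101 in the others, and the 2 anti-miR-196a replicates (0.101) were no closer to each other than anti-miR-196a replicate 2 was to control replicate 2 (0.0937). Pearson's r across probe sets was 0.988 to 0.989 with control replicate 1 and 0.999 in the other pairs. Poly-A spike-in controls, bacterial transcripts added before labelling, had a median over 12 probe sets of 2.94 in control replicate 1 and of 7.03, 7.08 and 6.90 in the others. Hybridisation controls, added afterwards, were at 10.44, 10.15, 10.25 and 10.15. The 3′ minus 5′ difference of the GAPDH control probe sets was 0.20, 0.05, -0.01 and 0.05, and that of beta-actin 0.11, 0.16, 0.16 and 0.19. No labelling batch is given by the labels. The group of 3 arrays with spike-in signal holds a single control, so every comparison within it sets 1 control against the 2 treated samples.

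**Figure D1:**
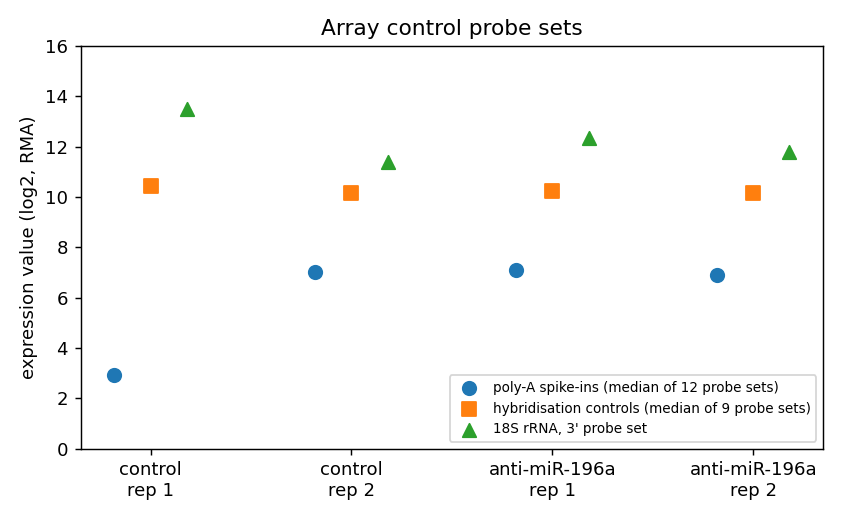
Log2 values of the poly-A spike-ins (median of 12 probe sets), the hybridisation controls (median of 9) and the 18S ribosomal RNA 3′ probe set on each of the 4 arrays, 1 point per array. The spike-ins lie at 2.94 in control replicate 1 and between 6.90 and 7.08 in the other arrays.

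The comparison of anti-miR-196a with control asked which transcripts respond when miR-196a-5p is inhibited in hypoxic glioblastoma cells. The mature microRNA was not analysed here, so its inhibition was not checked. NRAS, a RAS GTPase reported as a miR-196a target, averaged 10.24 ± 0.092 (SD, n = 2) in control and was 10.25 in both treated samples, a log2 difference of 0.0050 with a 95% interval of -0.19 to 0.20. HOXB8, the classic miR-196a target, was at 8.49 and 9.06 in control and at 9.04 and 9.11 in treated samples. HOXC8 was at 3.47 and 3.34 in control and 3.39 and 3.30 in treated samples, and HMGA2, a chromatin protein, at 5.05 in both controls and at 4.96 and 5.35. The cell cycle inhibitor CDKN1B was at 7.25 and 8.10 in control and at 8.13 and 8.12, a difference of 0.45 ± 0.35 (SE). Without control replicate 1 the difference was 0.025.

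Of 19 measured genes reported as miR-196a targets, 0 passed limma's test over all genes or adjusted over the list alone. A total of 10 were higher and 8 lower, with a median log2 difference of 0.0050 and a mean of 0.088. Camera gave an adjusted p of 0.418 for the list (0.614 with an estimated correlation), and the median was 0.015 without control replicate 1. BACH1, a transcriptional repressor, had a log2 difference of -0.26, HOXA9 one of -0.090, ING5, a chromatin regulator, one of 0.065 and HOXA7 one of 0.075. On control replicate 1 the poly-A spike-in probe sets, without their transcripts, read 2.47 to 4.08. All values of HOXA7 and HOXC8 lay within that range, so they are not shown to be above background. Those of BACH1 lay near its upper end, close to background. The differences of these genes say little about a response. NFKBIA, the NF-kB inhibitor, had a difference of -0.085. Without control replicate 1 the differences of NFKBIA, BACH1 and HOXA9 were -0.025, -0.16 and -0.045. In the authors' deposited table NRAS had a fold change of 1.02 with an unadjusted p of 0.81.

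**Figure D2:**
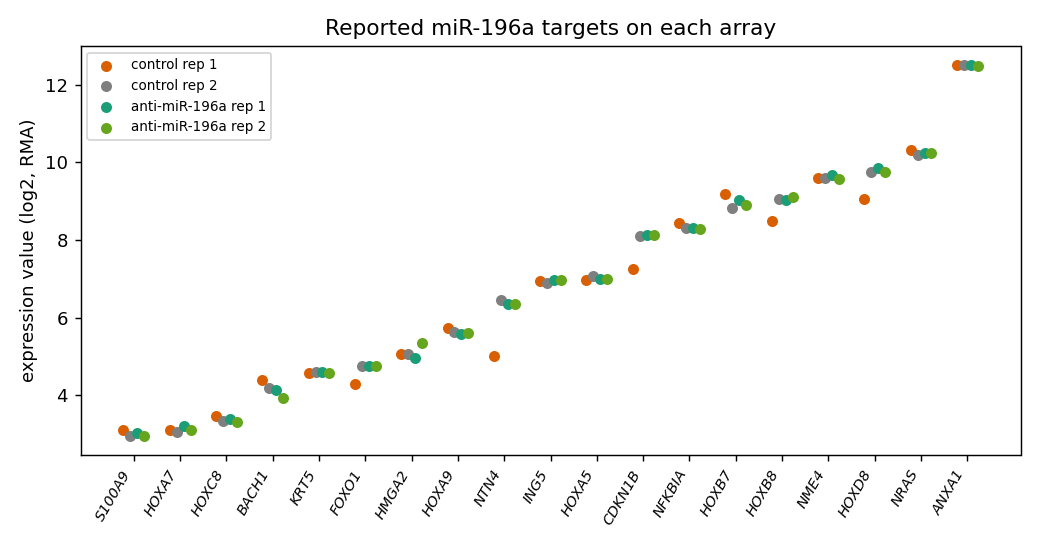
Log2 expression of the 19 reported miR-196a targets on each of the 4 arrays, 1 point per array, with genes ordered by level. CDKN1B lies at 7.25 in control replicate 1 and between 8.10 and 8.13 in the other arrays, and NRAS between 10.18 and 10.31 in all arrays.

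No gene passed the threshold, and the 30 genes named by the rule for the smallest unadjusted p had differences of at most 0.365 (log2). Higher in both treated samples were PAPOLA, a poly-A polymerase, with a difference of 0.215 ± 0.031 (SE), the DNA damage kinase ATM with 0.315 ± 0.065, the DNA glycosylase TDG with 0.15 ± 0.033 and the kinase subunit PRKACB with 0.165 ± 0.032. The others were TIE1, ARID5B, GLB1L2, IPP, TPMT, RPSAP9, TMEM200B, EMID1, HIP1, LYNX1 and OSGEPL1. Lower in both were EIF4E, the cap-binding translation factor, with -0.365 ± 0.069, EIF2S1, a subunit of initiation factor eIF2, with -0.20 ± 0.033, the retromer subunit VPS29 with -0.28 ± 0.041, the mitochondrial pyruvate carrier MPC2 with -0.165 ± 0.030 and the transcription factor POU2F1 with -0.33 ± 0.071. The others were PPP3R1, MREG, PYM1, RAB11FIP5, AP4B1, DUSP14, ANKRD13D, PBX2, TXLNA and CEP250. Ties between arrays lower some of these standard errors. PAPOLA, TDG, EIF2S1, GLB1L2, TPMT, LYNX1, OSGEPL1, PPP3R1, PYM1 and DUSP14 had identical values in both treated samples. TIE1, HIP1, RAB11FIP5 and TXLNA had them in both controls and MREG within each group, which makes the spread there 0. The values also rest on the brightest probe set. Over the mean of a gene's probe sets, 13 of the 30 differences were smaller by more than 1.5-fold or reversed, among them PAPOLA (0.054), TIE1 (0.061), RPSAP9 (0.040), ATM (0.19), EIF4E (-0.060), EIF2S1 (-0.12), VPS29 (-0.18), MPC2 (-0.11) and POU2F1 (-0.135), with HIP1 at -0.055. In the authors' deposited table EIF4E had a signed fold change of -1.27 with an unadjusted p of 0.0268.

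Limma gave 0 genes with an adjusted p under 0.05, and the smallest adjusted p was 0.705. At an unadjusted p under 0.05 it gave 253 genes, 105 higher and 148 lower, where 942 would be expected by chance. Groups did not overlap in 3348 genes, 17.8% of those tested. Chance would give 33.3% without tied values, but ties between arrays lower that share, and the other 2 splits of the arrays gave 3503 and 2939 genes. The median standard deviation per gene was 0.106 in control and 0.0283 in treated samples. Without control replicate 1, limma called 1065 genes. Of these, 1064 had identical values in both treated samples and so a spread of 0. Only 4 of the 18840 genes differed by at least 1.5-fold between control replicate 2 and the mean of the treated samples. Without control replicate 2, 5822 genes passed. In the authors' deposited table, 703 of 49293 probe sets had an unadjusted p under 0.05, where 2465 would be expected, and the smallest Benjamini-Hochberg value computed from those p-values was 0.863. Of its 88 probe sets with at least 2-fold change, 1 had a p under 0.05. In the per-array values without control replicate 1, 69 of the 88 kept their direction and 3 kept a difference of at least 0.5 (log2).

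Of the 28 gene lists, 9 passed with camera's preset correlation, 4 higher and 5 lower in treated samples. None passed with an estimated correlation (smallest adjusted p = 0.614) or with fry (smallest adjusted p = 0.0633), and none without control replicate 1. Without anti-miR-196a replicate 1 or 2, 1 and 0 lists passed. No member of any of the 28 lists passed limma's test over all genes or adjusted over the list alone.

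Interferon response genes were lower in the treated group. All 29 measured members had a lower mean, with a median log2 difference of -0.55 (camera adjusted p = 6.8e-05, and adjusted p = 0.614 with an estimated correlation). IFI27 averaged 10.16 ± 2.67 (SD, n = 2) in control and 7.98 ± 0.13 (SD, n = 2) in treated samples, IFI6 9.90 ± 1.92 and 8.17 ± 0.11, and RSAD2 4.42 ± 1.08 and 3.37 ± 0.29, where the treated values lay within the range of spike-in probe sets without their transcripts (2.47 to 4.08). ISG15, a ubiquitin-like modifier, was at 11.81 and 8.68 in control and at 8.63 and 8.65 in treated samples. IRF9, a subunit of the interferon-activated transcription factor ISGF3, had a difference of -0.305 ± 0.16 (SE). The list's median in control replicate 1 lay 1.13 above the mean of the other 3 arrays, and without that sample the median difference was -0.035.

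Cell cycle genes were lower in the treated group. All 30 measured G2/M and mitosis genes had a lower mean, with a median of -0.34 (camera adjusted p = 0.000305, and adjusted p = 0.614 with an estimated correlation). Of 30 G1/S and DNA replication genes, 28 were lower, with a median of -0.29 (adjusted p = 0.00419, and adjusted p = 0.614 with an estimated correlation). The mitotic cyclin CCNA2 had a difference of -0.415 ± 0.26 (SE), the kinetochore protein CENPF -0.52 ± 0.40, the checkpoint kinase BUB1 -0.32 ± 0.25 and KIF23, a motor of the cytokinetic midzone, -0.36 ± 0.23. The replication licensing factor CDT1 had a difference of -0.72 ± 0.51, GINS2 -0.365 ± 0.24 and RFC3 -0.345 ± 0.25. MKI67 had a difference of -0.425 ± 0.47, and 0.14 without control replicate 1. In that sample the G2/M and G1/S medians lay 0.67 and 0.60 above the other 3 arrays. Without it the median differences were 0.010 and 0.018.

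Hypoxia-induced genes were higher in the treated group. Of 30 measured members 24 were higher and 6 lower, with a median of 0.16 (camera adjusted p = 0.0078, and adjusted p = 0.614 with an estimated correlation). VEGFA, the angiogenic growth factor, was at 11.71 and 12.84 in control and at 12.84 and 12.90 in treated samples. EGLN3 had a difference of 0.99 ± 0.73 (SE), the stress-induced mTOR inhibitor DDIT4 0.48 ± 0.35 and the lipid droplet protein HILPDA 0.33 ± 0.21. CA9, a carbonic anhydrase used as a hypoxia marker, was at 9.50 and 9.32 in control and at 9.30 in both treated samples. Of 19 glycolysis genes, 14 were higher and 4 lower, with a median of 0.065 (adjusted p = 0.0479, and adjusted p = 0.614 with an estimated correlation). GAPDH had a difference of 0.29 ± 0.14 and ENO1 0.11 ± 0.068, while the hexokinases HK1 and HK2 had -0.090 ± 0.041 and -0.15 ± 0.081. In control replicate 1 the hypoxia and glycolysis medians lay at -0.315 and -0.15 relative to the other 3 arrays, and without it the median differences were 0 and -0.015. The glycolysis list did not pass with the dim-gene filter (adjusted p = 0.0566) or with quantile normalization applied again (adjusted p = 0.23).

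Stress response genes went both ways. Of 24 ATF4 and amino acid response genes, 20 were higher and 3 lower, with a median of 0.16 (camera adjusted p = 0.0078, and adjusted p = 0.614 with an estimated correlation). Of 21 unfolded protein response genes, 17 were higher and 4 lower, with a median of 0.070 (adjusted p = 0.023, and adjusted p = 0.614 with an estimated correlation). Of 18 heat shock proteins, 15 were lower and 3 higher, with a median of -0.165 (adjusted p = 0.0281, and adjusted p = 0.614 with an estimated correlation). ASNS, the asparagine synthetase, had a difference of 0.42 ± 0.30 (SE), the lipoprotein receptor VLDLR 0.44 ± 0.33, the amino acid transporter subunit SLC3A2 0.11 ± 0.060, the chaperone HSPA5 0.090 ± 0.055 and its cofactor DNAJB11 0.135 ± 0.090. Among heat shock proteins DNAJA1 had -0.16 ± 0.080, HSPB1 -0.17 ± 0.10, HSPD1 -0.23 ± 0.12 and HSPE1 -0.27 ± 0.17. The ATF4, unfolded protein and heat shock medians of control replicate 1 lay at -0.40, -0.16 and 0.28 relative to the other 3 arrays. Without it the median differences were -0.020, 0.0050 and -0.023. The unfolded protein list did not pass with the dim-gene filter (adjusted p = 0.0522), quantile normalization applied again (0.105) or the mean of probe sets (0.0974), nor heat shock proteins with the last (0.0723).

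NF-kB and inflammatory cytokine genes were slightly lower, with 18 of 24 members lower and 5 higher and a median of -0.040 (camera adjusted p = 0.0462, and adjusted p = 0.614 with an estimated correlation). The adhesion molecule VCAM1 was at 3.76 and 3.49 in control and at 3.13 and 3.18 in treated samples, all within the 2.47 to 4.08 read by spike-in probe sets without their transcripts and so not shown to be above background. The cytokine IL1A was at 5.54 in both controls and averaged 5.37 ± 0.014 (SD, n = 2) in treated samples. NFKB1 had a difference of -0.185 ± 0.12 (SE) and PTGS2, the inducible cyclooxygenase, 0.185 ± 0.12, with all values of PTGS2 also within the range of spike-in probe sets without their transcripts. Without control replicate 1 these differences were -0.050 and 0.060. The list did not pass with the dim-gene filter (adjusted p = 0.189) or with quantile normalization applied again (adjusted p = 0.0682). Here control replicate 1 lay 0.023 above the other arrays. Without it the median difference was -0.038, and the list did not pass (adjusted p = 0.258).

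**Figure D3:**
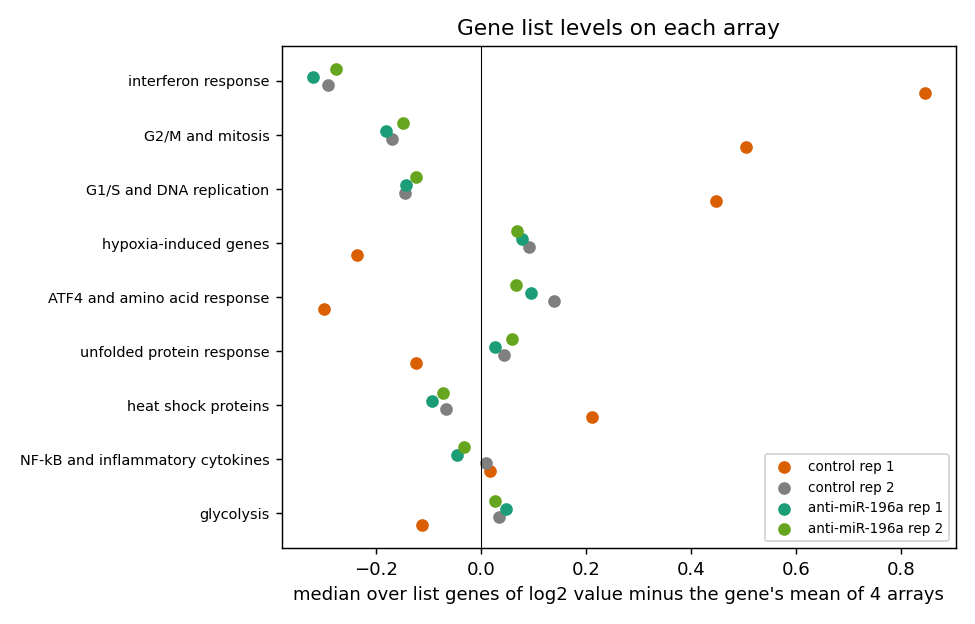
For each of the 9 lists past the threshold, the median over its genes of the log2 value minus the gene's mean over the 4 arrays, 1 point per array. For the interferon list control replicate 1 lies 1.13 above the other 3 arrays when the median is taken over each gene's difference from their mean.

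The remaining 18 lists did not pass. Camera's adjusted p was 0.0513 for cholesterol and lipid synthesis (18 of 24 members higher, median 0.19), 0.0701 for oxidative phosphorylation (21 of 29 lower, median -0.070) and 0.144 for RAS-ERK pathway output (16 of 23 lower, median -0.125). In the latter the feedback inhibitor SPRY4 had a difference of -0.585 ± 0.26 (SE), the transcription factors ETV4 and ETV5 -0.52 ± 0.28 and -0.095 ± 0.035, and the growth factor HBEGF -0.50 ± 0.28. Without control replicate 1 SPRY4, ETV4 and HBEGF had -0.28, -0.185 and -0.175, and the medians of these 3 lists were -0.0025, -0.0050 and -0.035. With quantile normalization applied again the cholesterol and oxidative phosphorylation lists passed (adjusted p = 0.0231 and 0.0112), and cholesterol also with the mean of probe sets (0.0448). Markers of endothelial, neural, immune and epithelial cells had adjusted p-values of 0.166, 0.295, 0.591 and 0.681 and medians of 0, 0, -0.015 and 0. For RAS-ERK components, PI3K-AKT and FOXO, extracellular matrix and EMT, and replication-dependent histones the adjusted p was 0.431, 0.41, 0.277 and 0.251, with medians of 0.055, 0.025, 0.085 and -0.115. For p53 targets it was 0.483 with 14 of 25 members lower, among them BAX (-0.255 ± 0.070), PMAIP1 (-0.19 ± 0.065) and CDKN1A (-0.125 ± 0.048). Glioma stem and progenitor markers had 0.334 with 13 of 22 lower, among them the Notch target HEY1 (-0.31 ± 0.054) and FUT4 (-0.215 ± 0.048). Autophagy and lysosome, HOX genes, apoptosis regulators, and migration and matrix degradation had 0.449, 0.563, 0.681 and 0.777. MicroRNA machinery had 0.681, with a median of -0.0050 although camera's direction was upward. TNRC6C, a partner of Argonaute, had a difference of 0.205 ± 0.068 and the exporter XPO5 -0.245 ± 0.085. Without control replicate 1 TNRC6C, XPO5 and PMAIP1 had 0.15, -0.155 and -0.12. The medians without it were 0 for RAS-ERK components, -0.025 for PI3K-AKT and FOXO, 0 for extracellular matrix and EMT, and -0.045 for replication-dependent histones.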

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

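In this part the tests of the spike-ins, of RNA degradation, of other cell types, of control replicate 1 as the source of the list differences, of a treatment effect in both replicates and of treatment at the size of the interferon, NF-kB and heat shock differences were chosen after the result was seen.

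Signal in probe sets outside the gene comparisons separated the arrays. The median of the poly-A spike-in probe sets was 4.068 (log2) higher in the 3 arrays that carry them than in control replicate 1. The 3′ probe set of dap was at 2.73 in that sample and at 10.43, 10.36 and 10.32 in the others. The 18S ribosomal RNA 3′ probe set was at 13.51 in control replicate 1 and at 11.40, 12.34 and 11.79 in the others.

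Control replicate 1 stood apart from the other 3 arrays. Degraded RNA is argued against by 3′ minus 5′ differences at most 0.17 (log2) above the other arrays, and a labelling run alone by interferon genes 1.127 higher in this sample, outside the range of random lists, so the RNA itself may have differed. A separate labelling run without spike-in RNA is a candidate explanation for the spike-ins, which lay at -4.068 relative to the others while the hybridisation controls lay at 0.257. RNA of immune, epithelial, neural or endothelial cells stays open. The marker medians reached at most the 65.96th percentile of random lists, but members went both ways. Of epithelial markers 7 were higher and 6 lower in this sample, and of immune markers 9 and 4. KRT8, KRT18 and CD68 were 0.97, 0.83 and 0.54 higher in this sample than in the others. The others also expressed KRT18, at 11.26, 11.16 and 11.20, and CD68, at 8.26, 8.23 and 8.26, so their rise alone does not point to other cells. A culture with a weaker hypoxic response stays open, since the list median of -0.315 lay at the 0.05th percentile of random lists, below the bound set beforehand, but 76.67% of hypoxia-induced genes were lower in this sample, less than the 90% also set, and no difference in handling that the labels name could be tested.

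The hypoxia, glycolysis, cell cycle, unfolded protein and ATF4 lists differed between the groups. Whether the treatment acted in both replicates cannot be decided from independent treated-minus-control differences. They correlated at -0.248 and -0.03778 across the 151 genes of these 6 lists (0.0593 and 0.0069 across all genes, where the test was first planned). In each pair 1 difference held control replicate 1. Over all genes, array pairs with that sample had a standard deviation of differences of 0.358 to 0.363, against 0.0937 to 0.102 in the others. A smaller treatment effect would hardly move such a correlation. The differences of the 6 lists may stem from control replicate 1 alone. Camera's direction, relative to other genes, reversed for all 6 lists without it and for 0 without each of the other 3 arrays. Of the medians themselves 4 reversed, that of hypoxia-induced genes was 0 and that of the unfolded protein response kept its sign at 0.0050. The loss of list calls with an array left out cannot decide this. Without a treated sample the only spread within a group is that between the controls, which holds control replicate 1. Without control replicate 2, control replicate 1 stands alone against the treated pair.

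The interferon, NF-kB and heat shock lists, all 3 lower in treated samples, kept their direction without control replicate 1, and none passed. Treatment at the size of the interferon and heat shock differences is argued against: without that sample the medians were -0.035 (bootstrap interval -0.060 to -0.025) and -0.0225 (-0.0575 to 0.015), against -0.55 and -0.165 with it. The NF-kB difference cannot be told apart from a treatment effect, since its median was -0.0375 (-0.065 to -0.025) against -0.040. A smaller effect on the other lists stays open, and an effect of the full size is not excluded, because these values rest on 1 control sample. The intervals were taken over genes and hold no spread between samples.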

How the results depend on the processing

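In this part the comparisons among the 3 arrays with spike-in signal and the correlation over bright genes were chosen after the result was seen. The gene count was 0 under the replicate block, the dim-gene filter, the intensity-dependent prior, both normalizations, the mean of probe sets, all probe sets and the 1.5-fold threshold. Leaving out 1 array gave 0 to 5822 genes (1065 without control replicate 1, 5822 without control replicate 2). A lone sample is then assumed to vary like the other group, and identical values in the remaining pair give a spread of 0. List calls numbered 9 with the replicate block, 6 with the filter, 8 with quantile normalization, 8 with the mean of probe sets, 0 with an estimated correlation, 0 with fry and 0 to 9 with an array left out (0 without control replicate 1, 9 without control replicate 2, 1 and 0 without anti-miR-196a replicates 1 and 2). Of the 9 calls, 8, 6, 6 and 7 were shared by the first 4 settings. The block lost NF-kB (adjusted p = 0.0837) and added cholesterol synthesis (0.024), the filter lost NF-kB, glycolysis and the unfolded protein response, quantile normalization lost the same lists and added cholesterol synthesis and oxidative phosphorylation, and the mean of probe sets lost the unfolded protein response and heat shock proteins and added cholesterol synthesis. Whether the replicate numbers pair the samples cannot be decided. Across genes, replicate 1 minus replicate 2 correlated at r = 0.0482 between control and treated samples. These differences had standard deviations of 0.358 in control and 0.101 in treated samples. The shift of control replicate 1 could therefore hide a pairing. The lowest correlation between arrays was 0.9885, 0.9652 over bright genes, and 0.9885 to 0.9989 with an array left out. The seed-site test and its alternatives were not run, nor was one on per-sample values of the authors' table, which was used only for group means.

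These reversed, and the cause was not tested. With the replicate block, migration and matrix degradation (adjusted p = 0.9729). With quantile normalization, NRAS (-0.01125). With the mean of probe sets, NRAS (-0.040), HIP1 (-0.055), HOXA7 (-0.030), HMGA2 (-0.1375), HSPD1 (0.02643) and the lists apoptosis regulators, migration and matrix degradation, and HOX genes (each 0.9943) and microRNA machinery (0.7076). With fry, HOX genes (0.9399). With 1 array left out, 22 results reversed in at least 1 case, with these ranges. Log2 differences ran from -0.060 to 0.070 for NRAS, -0.125 to 0.0050 for HOXC8, -0.090 to 0.30 for HMGA2, -0.99 to 0.14 for MKI67 and -0.95 to 0.060 for KRT8. Adjusted p ran from 0.0009283 to 0.8363 for hypoxia-induced genes, 0.02102 to 0.612 for glycolysis, 8.332e-06 to 0.2582 for G1/S, 4.821e-09 to 0.2582 for G2/M, 0.02703 to 0.8386 for the unfolded protein response, 0.0005523 to 0.3605 for ATF4 and 0.01166 to 0.6369 for cholesterol synthesis. It ran from 0.2302 to 0.6884 for p53 targets, 0.5799 to 0.8431 for apoptosis regulators, 0.2335 to 0.4897 for PI3K-AKT, 0.1113 to 0.8363 for extracellular matrix, 0.264 to 0.8575 for migration, 0.5013 to 0.9109 for HOX genes, 0.2153 to 0.7896 for autophagy, 0.3605 to 0.789 for microRNA machinery, 0.1505 to 0.8431 for immune and 0.5319 to 0.9109 for epithelial markers.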

Other observations

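In this part the search for the widest gaps between groups, the comparisons of single arrays and the bootstrap interval were chosen after the result was seen.

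AKR1C1 and AKR1C2, aldo-keto reductases of steroid and carbonyl metabolism, were lower in both treated samples than in both controls. AKR1C1 was at 9.73 and 7.27 (log2) in control and at 6.18 and 6.5 in treated samples, and AKR1C2 at 9.33 and 7.24 against 6.77 and 6.75. The gap between the lowest control and the highest treated sample was 0.77 for AKR1C1, the widest of all 18840 genes, and 0.47 for AKR1C2. TAF9B, a transcription factor subunit, had the widest gap upward, at 4.25 and 4.30 in control and 4.78 and 4.91 in treated samples, followed by ENPP2, the enzyme autotaxin, with a gap of 0.36. The control values of both genes lay just above the 2.47 to 4.08 read by spike-in probe sets without their transcripts. They are therefore close to background, and the size of these gaps is uncertain. Limma's adjusted p was 0.705 for all of them. Without control replicate 1 the differences of AKR1C1 and AKR1C2 were -0.93 and -0.48. Gaps of at least 0.3 were found in 10 genes under the real split of the samples and in 16 and 5 under the other 2 splits, whose widest gaps were 0.52 and 0.35. With 3 splits in all, no share under 0.05 can be reached.

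For AKR1C1 and AKR1C2, a lower NRF2 response in the treated arrays cannot be told apart from other causes. The other 22 measured NRF2 targets had a median difference of -0.02 (log2) against control replicate 2, at the 8.45th percentile of random lists. That lies within the central range set beforehand to count against this explanation, but the bootstrap interval of -0.0425 to -0.0050 extended past its lower bound of -0.0275. Probes shared within the AKR1C family stay open too: 3 of 6 measured family genes and pseudogenes were lower in both treated samples, and the gap of AKR1C3 was 0.03. AKR1C4, AKR1C6P and AKR1C8P, not lower, read 2.46 to 3.34. That is the level of spike-in probe sets without their transcripts, so a fall could not be seen in them. Further AKR1C2 probe sets had gaps of 0.26 and -0.05, the second at that level too. Either explanation may account for part of the pattern, and so may chance in the 2 treated samples.

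Among the 3 arrays with spike-in signal, each was set against the other 2. With 3 such splits no share under 0.05 can be reached, so the values are given without a verdict. Limma called 1065 genes for control replicate 2 against the treated pair, 2337 for anti-miR-196a replicate 1 against the other 2 arrays and 0 for anti-miR-196a replicate 2. Identical values in the pair were found for 99.9% of the 1065 calls and 99.2% of the 2337. A total of 5107 genes had the same value, to 2 decimals, in both treated samples, and 1317 differed by 0.01. At least 1.5-fold differences numbered 4, 2 and 0. Of the 28 list medians, 7 lay outside the central 95% of random lists with control replicate 2 as the single array, 2 with anti-miR-196a replicate 1 and 8 with anti-miR-196a replicate 2. The interferon list's median was 0.035 higher in control replicate 2 than in the treated pair, and the corresponding value was -0.015 for anti-miR-196a replicate 1 and 0 for anti-miR-196a replicate 2. RAS-ERK pathway output had medians of 0.035, 0.010 and -0.055 in the same order.

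Splitting the 4 arrays 2 against 2 gave 253 genes with an unadjusted p under 0.05 for the real groups and 350 and 277 for the other splits, with 0 genes past the adjusted threshold in each case.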
